A study of Arabidopsis thaliana with 7 samples.

How the data were processed

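Gene expression was measured in developing seeds of Arabidopsis thaliana with Affymetrix arrays, 1 array per sample. Per the labels, 4 samples came from wild-type plants of the Columbia accession and 3 from plants carrying the myb5-1 allele, all at globular to walking-stick embryo stages. The seeds were dissected out of the siliques, and total RNA was amplified by repeated cycles of oligo(dT)-primed cDNA synthesis and in vitro transcription into biotin-labelled cRNA, per the labels' protocols. Per the series design text, the samples of each genotype are biological replicates. Amplification from an oligo(dT) primer favours the 3' ends of polyadenylated transcripts, so transcripts without a poly(A) tail are measured less directly.

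The deposited values are 1 linear signal intensity per probe set and array, for 22810 probe sets. The software that made these deposited intensities is not given in the sources used here. From the values, the mean after dropping 2% of the probe sets at each end was 150.01 in all 7 arrays, so each array had been scaled to one target before deposit. Such scaling removes differences in overall brightness, and it cannot remove differences that depend on intensity or on the probe set. No detection call was used here, so a low signal has no stated limit of detection, and between 29.2% and 32.4% of the probe sets of each array lay below an intensity of 16. The precision of every value is limited by the number of arrays.

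The 64 control probe sets were left out, which left 22746 probe sets for testing. Intensities were turned into log2(intensity + 16). A log2 difference on this scale understates the change of dim probe sets. The medians of the arrays ran from 6.02 to 6.14 on this scale, a spread of 0.12 that exceeded the limit of 0.1 set before the data were examined, so the arrays were quantile normalized. The genotypes were compared with limma (version 3.58.1, in R 4.3.3), as lmFit and eBayes with genotype as the only term and no filter on dim probe sets, and p-values were adjusted by Benjamini-Hochberg over all probe sets tested, with a threshold of 0.05. All adjusted p-values of single probe sets below come from this limma fit unless another is named. Levels are given as the mean deposited intensity ± SD, and differences are myb5 minus wild type on the normalized log2 scale with the standard error of the fit. Exact two-sided permutation tests used all 35 splits of the 7 arrays into 4 and 3, for which the smallest possible p is 0.0286.

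Gene names were taken from the annotation table of the array and brought up to date through a table of Arabidopsis genes. Of the probe sets tested, 13513 named exactly 1 gene, 503 named several and 8730 are unnamed here, and 13436 of those naming 1 gene were found in the gene table. Only probe sets naming 1 gene were given a gene name. The level of MYB5 in each sample, planned as a check of the labels, was not analysed here, because the tables used give no probe set under its name.

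In all, 15 lists with 198 members were fixed before the data were examined, and 28 members had a probe set naming that gene alone. Lists with at least 3 measured members were tested with camera at a preset inter-gene correlation of 0.01. The genes named in the text followed a rule fixed at the same time. Among probe sets naming 1 gene, passing the threshold and with no overlap between the genotypes, it takes the 10 with the largest rise and the 10 with the largest fall; where fewer than 10 pass, all that pass, filled to 5 in that direction by the smallest unadjusted p and said not to pass. In each list it takes up to 4 members with the largest difference among those passing or, where none passes, the 2 with the smallest p. Features named outside this rule are said to have been chosen after their values were seen.

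Alternatives fixed beforehand were the intensities as deposited, centring on the array median, leaving out the dimmest 30% or 50% of the probe sets, pseudocounts of 1 and 64, the replicate number as a block, eBayes with trend and robust settings, array weights, an added size threshold of 1 on the log2 scale, camera with an estimated correlation, fry, and leaving out each array in turn. Alternatives chosen after seeing the data were a term for a set of 3 arrays that stood apart from the other 4, fits within each of those sets, the counts of probe sets at least 2-fold apart, with no overlap or with an unadjusted p under 0.05 leaving out each array, and further gene lists for late seed maturation and for plastid-encoded and mitochondrion-encoded genes. The late seed maturation list was put together after values of its members had been seen, and the others after a scan of the median difference by chromosome.

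The fit was tested on simulated data for 22746 probe sets with the sizes of these groups. Changes of 1 on the log2 scale were recovered for 39 of 67 probe sets. Changes of 2 were recovered for 60 of 67 and changes of 4 for 62 of 66. There were 6 false calls, and the sign was right for 100% of the changed probe sets of each size. The simulated noise was independent between probe sets, and many changes were planted at once, which eases the adjusted threshold. The real arrays shared differences across probe sets and gave 1 call, so these shares can overstate what could be found here.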

Results

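The transcripts of developing seeds were compared between wild-type plants of the Columbia accession (n = 4 arrays) and plants with the myb5-1 allele (n = 3 arrays). MYB5 is a MYB transcription factor known for roles in the seed coat, where it acts on mucilage and tannin formation. The seeds spanned globular to walking-stick embryo stages, and whole seeds hold embryo, endosperm and seed coat together. The level of MYB5 itself was not analysed here. The arrays had been scaled to one trimmed mean before deposit, but their medians still differed by genotype. Median intensities were 49.0 to 50.8 in wild type and 52.2 to 54.4 in myb5, with no overlap. Quantile normalization removes such a difference, whatever its source. The question set by the design is which genes are differentially expressed between the genotypes.

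Across the seed transcriptome, 1 probe set passed the threshold between the genotypes, and it was lower in myb5. This probe set, 256985_at, is unnamed here. Its intensity was 673 ± 158 in wild type (SD, n = 4) and 22.5 ± 6.13 in myb5 (SD, n = 3). The log2 difference was -4.19 with a standard error of 0.21 (limma adjusted p = 0.0019), and every myb5 array lay below every wild-type array. The exact two-sided permutation p was 0.0286, the smallest that 35 splits allow. This p adds no support, because a lack of overlap already puts it at or next to that floor. No probe set passed as higher in myb5, while 788 of 22746 probe sets (3.46%) had an unadjusted limma p under 0.05, against 5% by chance. That count lay on either side of chance: it was 514 (2.26%) without myb5 replicate 2, 1582 (6.96%) without myb5 replicate 1, 1362 with the replicate number as a block, 1245 with array weights and 1249 (5.49%) with a term for wild-type replicates 1 and 2 and myb5 replicate 1, which stood apart. The one call was not made with the replicate number as a block, where the difference was -4.05 (limma adjusted p = 0.18). In that fit wild-type replicate 4 has no myb5 partner, and fewer residual degrees of freedom remain. Without wild-type replicate 4 and without a block the difference was -4.04 (limma adjusted p = 0.0062). Nor was the call made among wild-type replicates 3 and 4 with myb5 replicates 2 and 3 alone, where the difference was -4.45 (limma adjusted p = 0.18). Among the remaining 3 arrays alone, which hold a single myb5 array, the difference was -3.91, and that fit cannot judge the call.

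Other unnamed probe sets stood apart in intensity without passing, and those given here were chosen after their values were seen. Probe set 267122_at had an intensity of 833 ± 681 in wild type (SD, n = 4) and 13.1 ± 7.28 in myb5 (SD, n = 3), a log2 difference of -4.52 (limma adjusted p = 1.00). Its wild-type intensities were 1724 and 1002 in replicates 1 and 2, and 245 and 362 in replicates 3 and 4. Every myb5 array lay below them, at 5.99 to 20.55. With a term for wild-type replicates 1 and 2 and myb5 replicate 1 its log2 difference was -4.35, and it still did not pass (limma adjusted p = 0.35). Probe set 259737_at had 20.5 ± 5.80 in wild type and 117 ± 18.1 in myb5, a log2 difference of 1.82 (limma adjusted p = 0.10). Probe set 257483_at was dim in both genotypes, at 4.54 ± 2.58 and 23.5 ± 2.0, with a log2 difference of 0.88 (limma adjusted p = 1.00). These sizes depend on the added constant. With pseudocounts of 1 and 64 the log2 differences were 2.41 and 1.07 for 259737_at and 2.11 and 0.33 for 257483_at. They were -5.68 and -3.19 for 267122_at and -4.92 and -3.09 for 256985_at.

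**Figure D1:**
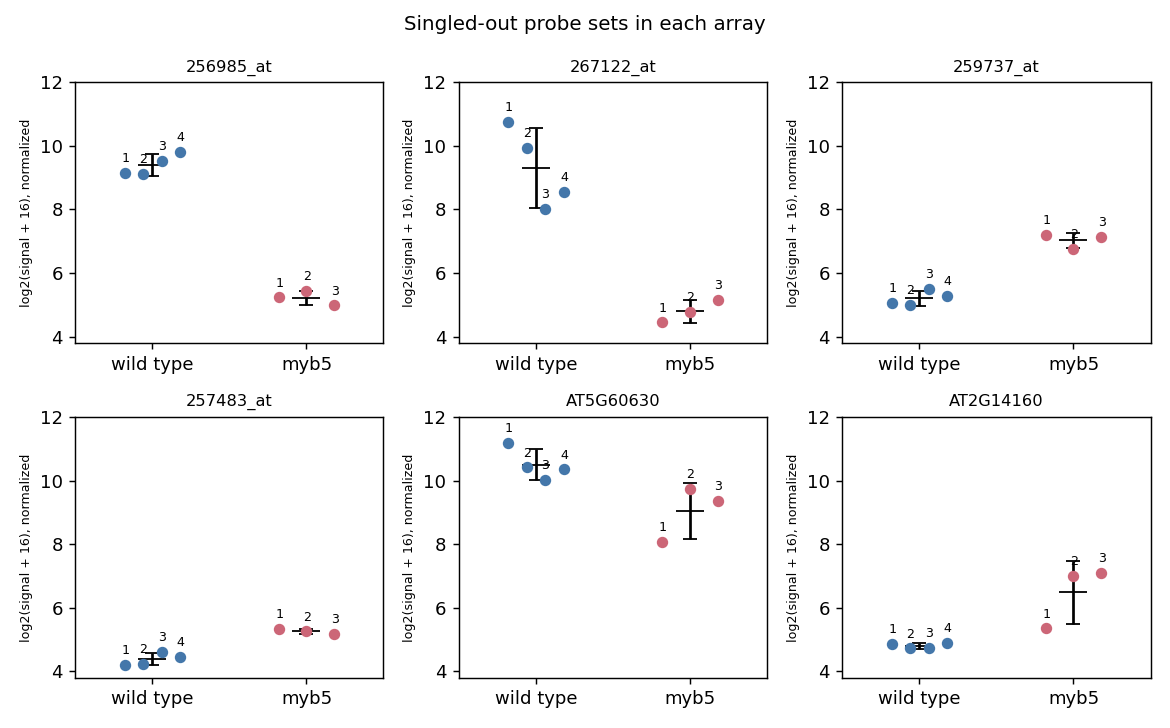
Each panel plots 1 probe set, with genotype on the horizontal axis and the quantile-normalized log2(intensity + 16) of each array on the vertical axis; points are arrays numbered by replicate, and bars are the mean ± SD of 4 wild-type and 3 myb5 arrays. For 256985_at the deposited intensities were 538 to 876 in wild type and 16.5 to 28.7 in myb5.

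Counting size alone, 41 probe sets differed by at least 2-fold, and 14 of these had no overlap between the genotypes, 4 higher and 10 lower in myb5. These counts moved when single arrays were left out, where fewer arrays also overlap less often by chance. Without myb5 replicate 1, 143 of 331 had no overlap. The counts were 45 of 159 without wild-type replicate 3 and 20 of 108 without wild-type replicate 4. They were 14 of 65 without myb5 replicate 2 and 27 of 47 without myb5 replicate 3. They were 13 of 28 without wild-type replicate 1 and 13 of 30 without wild-type replicate 2, near the count with all arrays. Without myb5 replicate 1, no myb5 array belongs to the arrays that stood apart, so genotype partly takes up that split. Over all probe sets 990 (4.35%) had no overlap, against 5.71% by chance, and without myb5 replicate 1 the share was 17.3%, against 13.3% by chance. Of the 14, 9 are unnamed here and 5 name 1 gene; these 5 were chosen after their values were seen and did not pass the threshold (limma adjusted p = 1.00 for each). AT5G60630 had an intensity of 1498 ± 542 in wild type (SD, n = 4) and 569 ± 293 in myb5 (SD, n = 3), a log2 difference of -1.44, or -0.94 without myb5 replicate 1. The log2 differences of AT5G18130 and AT4G33810 were -1.22 and -1.01. AT3G28550 had a log2 difference of 1.28, or 0.82 without myb5 replicate 2, and its myb5 intensity was 50.4 ± 40.8 (SD, n = 3). AT2G14160 had a log2 difference of 1.68, with intensities of 11.3 ± 1.2 in wild type and 88.7 ± 54.7 in myb5. Its myb5 intensity was 25.6 in replicate 1, against 116 and 124 in replicates 2 and 3. Without myb5 replicate 1, AT2G14160 passed the threshold at a log2 difference of 2.25 (limma adjusted p = 0.0127).

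No probe set naming 1 gene passed, so the genes with the smallest unadjusted p in each direction are given as values. AT1G47520, AT5G29040, AT3G18250, AT2G19100 and GH9B6, an endoglucanase family gene, had log2 differences of 0.62, 0.49, 0.81, 0.46 and 0.51. Their mean intensities ran from 1.69 to 9.25 in wild type and from 9.07 to 25.9 in myb5. AT1G78470, AT4G28703, AT2G39540, AT3G15357 and GSTU23, a glutathione transferase gene, had log2 differences of -0.74, -0.71, -0.78, -0.49 and -0.60. Their mean intensities ran from 11.3 to 34.5 in wild type and from 2.76 to 18.9 in myb5. The limma adjusted p was 1.00 for each of these 10 genes, and most of these intensities lay near or below the added constant of 16.

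Genes that make or modify seed mucilage, the pectin-rich layer released by the seed coat, had 8 measured members, and 0 passed over all probe sets or adjusted over the list alone. Their mean log2 difference was -0.05 (SD 0.26 across genes), 3 were above 0, and camera gave an adjusted p of 0.97. UUAT1, a Golgi UDP-uronic acid transporter, had an intensity of 755 ± 182 in wild type (SD, n = 4) and 547 ± 84.9 in myb5 (SD, n = 3), a log2 difference of -0.42 (standard error 0.21). PME58, a pectin methylesterase, had a log2 difference of 0.29, smaller than the SD of 0.34 among wild-type arrays. SBT1.7, a subtilase of the seed coat chosen after its values were seen, was among the brightest members at 6152 ± 1082 in wild type and 6081 ± 875 in myb5.

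Genes for proanthocyanidins, the tannins of the seed coat, had 3 measured members, and 0 passed over all probe sets or adjusted over the list alone. Their mean log2 difference was 0.17 (SD 0.18 across genes; camera adjusted p = 0.97). This mean depended on which arrays were included. It was 0.46 without myb5 replicate 1, 0.37 without wild-type replicate 3 and 0.26 without wild-type replicate 4. It was 0.05 without myb5 replicate 2, 0.04 without wild-type replicate 2, 0.018 without wild-type replicate 1 and 0.0086 without myb5 replicate 3. The mean normalized log2 level of the list was 9.96 to 10.03 in wild-type replicates 1 and 2 and myb5 replicate 1. In the other 4 arrays it was 10.67 to 11.02. With a term for that split the mean log2 difference was 0.03. BAN, which encodes anthocyanidin reductase, had an intensity of 4279 ± 1869 in wild type (SD, n = 4) and 5279 ± 1639 in myb5 (SD, n = 3), a log2 difference of 0.38 with a standard error of 0.36. TT15, a sterol glucosyltransferase gene, had a log2 difference of 0.06. DFR, which encodes dihydroflavonol reductase and was chosen after its values were seen, had a log2 difference of 0.07 with a standard error of 0.56. BAN and DFR differed more between arrays of 1 genotype than between genotypes: DFR had intensities of 1383 to 2143 in wild-type replicates 1 and 2 and myb5 replicate 1, and of 3906 to 5381 in the other 4 arrays.

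Genes of the anthocyanin pathway had 4 measured members, and 0 passed over all probe sets or adjusted over the list alone. Their mean log2 difference was -0.016 and their median 0.02, and camera pointed up (adjusted p = 0.97), so mean and test differed in sign. UGT78D2 and UGT78D1, both flavonoid glycosyltransferase genes, had log2 differences of -0.17 and 0.07. Endosperm markers had 3 measured members, and 0 passed over all probe sets or adjusted over the list alone; their mean log2 difference was -0.0046 (camera adjusted p = 0.97). IKU2, a receptor kinase gene of endosperm growth, and AGL62, a MADS-box gene of endosperm cellularization, had log2 differences of 0.21 and -0.16 at mean intensities between 4.05 and 9.56.

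In 7 lists only 1 or 2 members were measured, and 0 members passed over all probe sets or adjusted over the list alone. Among regulators, DF1 of the seed coat list had a log2 difference of 0.30, and TRY and MYC1 of the trichome and root hair list had 0.18 and -0.31. The embryo marker CLV3 had -0.17, the fruit wall marker ALC 0.35, and the photosynthesis gene RCA -0.49 with a standard error of 0.47. PDF1.2 and COR15A of the stress list had log2 differences of 0.10 and -0.12, and the reference genes TIP41 and SAND had 0.10 and -0.10. The general flavonoid, suberin and cutin, seed maturation and cell cycle lists had 0 measured members. Of the 28 members measured over all lists, 0 had an unadjusted limma p under 0.05, and the smallest was 0.080. The call counts of 0 hold for 28 of 198 list members and leave the others open. The 4 list tests kept an adjusted p of at least 0.86 with an estimated correlation and with fry.

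The largest differences between arrays cut across genotype. The first principal component held 56.8% of the variance and separated wild-type replicates 1 and 2 and myb5 replicate 1 from the other 4 arrays. Pearson correlations across probe sets, which are not independent replicates, were 0.974 to 0.985 within these sets of arrays and 0.933 to 0.963 between them. Late seed maturation genes, chosen after values had been seen, differed along this split: PAP85, a vicilin-like storage protein gene, had intensities of 376 to 1979 in the 3 arrays and 13.8 to 21.9 in the other 4, and OLEO3, an oleosin gene, had 4435 to 5364 and 610 to 1469. The 3 arrays hold 2 of 4 wild-type and 1 of 3 myb5 samples. With a term for this split the single call remained 256985_at, at a log2 difference of -4.24 (limma adjusted p = 0.00082). Of 6 control pairs that compare the 5' and 3' ends of a transcript, 1 separated the 3 arrays, a GAPDH pair with a 5'/3' ratio of 0.156 to 0.208 against 0.081 to 0.093 in the other 4, and 1 separated the genotypes: another GAPDH pair had a 5'/3' ratio of 0.584 ± 0.034 in wild type (SD, n = 4) and 0.505 ± 0.011 in myb5 (SD, n = 3; exact permutation p = 0.0286, adjusted over the 6 pairs 0.17).

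**Figure D2:**
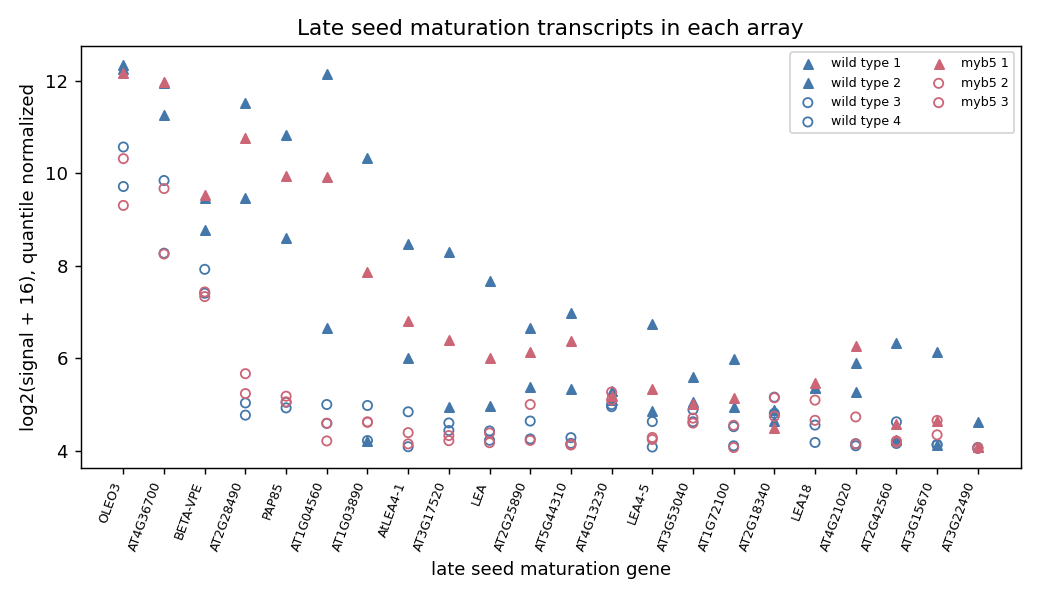
The plot gives the quantile-normalized log2(intensity + 16) of 22 late seed maturation genes on the vertical axis, with 1 gene per position; filled triangles are wild-type replicates 1 and 2 and myb5 replicate 1, and open circles are the other 4 arrays, coloured by genotype. For 17 of the 22 genes all 3 triangles lie above all 4 circles; the list was chosen after values had been seen.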

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

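The tests that weigh explanations below, the counts over splits and the rules that decide them were chosen after the results had been seen. The search for far arrays was not, but part of the probe sets it covered had been picked by their values. An array far from the others of its genotype was found in 4 of the 37 wild-type groups tested. Chance gives about 1 in 20 for probe sets not picked by their values, so that rate is no measure here. On the normalized log2 scale, wild-type replicate 1 lay at 4.26 for AT2G19100, against 4.11 to 4.13 in the other wild-type arrays, and at 4.33 for GH9B6, against 4.09 to 4.11. Wild-type replicate 3 lay at 4.68 for IKU2, against 4.26 to 4.33, and at 4.11 for CLV3, against 4.50 to 4.55. Of the 64 control probe sets, 0 passed an adjusted limma p of 0.05, and 1 had an unadjusted p under 0.05.

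The count of 1 changed probe set was reached by 4 of the 35 splits of the 7 arrays, the real one included, so chance cannot be excluded for the count over these splits. The highest other split called 2885 probe sets; it sets wild-type replicates 1 and 2 and myb5 replicate 1 against the other 4 arrays, which points to a structure of the samples. Among the 18 splits that, like the real one, put 1 of those 3 arrays in the smaller group, the real split alone made a call, with 0 in the highest other; 18 splits are too few for a share under 0.05. The count of 14 probe sets at least 2-fold apart with no overlap was reached by 12 of the 35 splits, with 911 in the highest other split, so chance cannot be excluded there either; of the 18 splits just named, 2 reached it, with 15 in the highest other.

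Wild-type replicates 1 and 2 and myb5 replicate 1 stood apart from the other 4 arrays. A candidate explanation is a larger share of late-stage seeds in those samples: 17 of 22 late seed maturation genes were higher in all 3 arrays than in all 4 others, and 20 of 26 with 4 other candidates that had been dropped put back. This leaves the explanation open, because the list was assembled after values had been seen, with 3 genes met in a ranking along the split left out, and the 2.86% that a random split would give is no measure of chance for a split read from the data. RNA degradation or shorter amplification products stay open too: of 6 control pairs 1 separated the 3 arrays by its 5'/3' ratio, a GAPDH pair at 0.156 to 0.208 against 0.081 to 0.093 in the other 4, and the overlap of the other ratios excludes nothing. A batch of growth, amplification or scanning that ran along the same split was not tested, because the labels used here give none.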

How the results depend on the processing

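The settings confined to some arrays, the term for a set of arrays and all settings of the plastid list were chosen after seeing the data. Probe set 256985_at was called alone in the fixed alternatives other than the replicate block and the fit without myb5 replicate 1, with an adjusted p from 0.00037 to 0.026 over the settings that called it. Deviations from the genotype mean correlated at 0.63, -0.30 and 0.55 between same-numbered replicates 1, 2 and 3. Replicates 1 and 3 each lay within 1 set of arrays in both genotypes, and replicate 2 did not. These correlations follow the sets and cannot tell whether the numbers pair the samples. With the replicate block, which leaves fewer residual degrees of freedom, 0 probe sets were called, 0 of them lower (256985_at at -4.05, limma adjusted p = 0.18). Leaving out each array gave 1 to 2 calls, 0 to 1 higher and 1 lower; AT2G14160 (2.25) was the added call without myb5 replicate 1. Wild-type replicates 3 and 4 with myb5 replicates 2 and 3 alone gave 0 calls, 0 of them lower, with fewer samples. The remaining 3 arrays alone cannot judge the call, since their lone myb5 array is assumed to vary like the wild-type arrays. The 4 lists tested passed in 0 settings. The proanthocyanidin mean was 0.0086 to 0.46 leaving out each array and 0.03 with the set term. The means of the other lists changed sign, for causes that were not tested. Against reported means of -0.016, -0.0046 and -0.05, the anthocyanin mean was 0.014 as deposited, 0.00032 with a pseudocount of 1, 0.060 with the set term, 0.24 in the 3 arrays alone and -0.23 to 0.12 leaving out each array. The endosperm mean was 0.053 as deposited, 0.031 with a pseudocount of 1, 0.0061 with the replicate block, 0.066 with array weights, 0.040 in the 4 arrays alone and -0.12 to 0.059 leaving out each array. The mucilage mean was 0.032 with the replicate block and -0.14 to 0.030 leaving out each array. Single genes that changed sign did not pass either: UGT78D1 was -0.034 with median centring, -0.078 in the 4 arrays alone and -0.017 to 0.21 leaving out each array; PDF1.2 was -0.027 with array weights, -0.027 in the 4 arrays alone and -0.050 to 0.31 leaving out each array; TRY was -0.017 and UGT78D2 0.11 in the 3 arrays alone. Leaving out each array moved UGT78D2 from -0.52 to 0.14, MYC1 from -0.56 to 0.032 and COR15A from -0.24 to 0.062; without a change of sign, RCA ran from -0.95 to -0.13, ALC from 0.22 to 0.55, BAN from 0.21 to 0.67, TRY from 0.0033 to 0.29, IKU2 from 0.012 to 0.36, AGL62 from -0.30 to -0.059, PME58 from 0.16 to 0.46, DF1 from 0.18 to 0.42, TT15 from 0.024 to 0.13, CLV3 from -0.27 to -0.12, SAND from -0.24 to -0.0095, AT3G28550 from 0.82 to 1.64 and AT5G60630 from -1.79 to -0.94. The plastid ribosomal mean was above 0 in every setting run, 0.43 to 0.64 leaving out each array, but its p with an estimated correlation, adjusted over 6 lists, lay at or over 0.05 in 12 of 19 other settings, and ran from 0.027 to 0.15 leaving out each array. With the set term RCA was -0.28, BAN 0.23, MYC1 -0.18 and UGT78D2 -0.0093, each nearer 0 than reported. PDF1.2, COR15A, SAND and SBT1.7 moved away from 0 with it, to 0.14, -0.14, -0.13 and -0.05. DFR changed sign with it, to -0.18. The MYB5 level could give no value. Signals near 16 limit what dim probe sets can show.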

Other observations

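All tests in this part were chosen after the results they weigh had been seen. Some genes of the fixed lists also differed along the split of 3 and 4 arrays; those named here were chosen after their values were seen, and no list was tested along it. PMEI14, a pectin methylesterase inhibitor gene, had intensities of 3980 to 4239 in those arrays and 7113 to 10112 in the other 4, and BAN had 2684 to 3424 and 4681 to 6754. MUCI10, a galactomannan galactosyltransferase gene of mucilage, went the other way, at 819 to 1438 and 327 to 691. Of the 28 measured members of the lists fixed beforehand, 5 were higher and 7 lower in all 3 arrays than in all 4 others, and the 2.86% that a random split would give in each direction is no measure of chance for a split read from the data.

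Plastid-encoded ribosomal protein genes were higher in myb5 for 15 of 15 probe sets, with a mean log2 difference of 0.56 (SD 0.22 across genes). This was noticed while scanning the median difference of each chromosome, and the list was made afterwards. The difference was 0.95 for rpl22, 0.71 for rps3 and 0.17 for rpl33. Over all probe sets 0 of the 15 passed, 5 passed when adjusted over the list alone, and 8 had no overlap between the genotypes. At the preset correlation of 0.01, camera gave an adjusted p of 1.99e-15 over the 6 lists made afterwards. The estimated correlation between members was 0.21, so this p overstates the evidence. With the estimated correlation, the camera adjusted p was 0.042. That adjusted p was 0.063 on the intensities as deposited, 0.09 with a term for the 3 arrays, 0.09 without wild-type replicate 2, 0.12 without wild-type replicate 3, 0.15 without wild-type replicate 4, 0.13 without myb5 replicate 1 and 0.07 without myb5 replicate 3, and over all 19 other settings it ran from 0.027 to 0.72. Plastid photosynthesis genes had a mean log2 difference of 0.02 over 33 probe sets (0.12 with the term for the 3 arrays), plastid NDH complex genes 0.24 over 10 and plastid RNA polymerase genes 0.30 over 4, and with an estimated correlation their adjusted p was 0.79, 0.17 and 0.49. Mitochondrion-encoded genes had a mean of 0.32 over 23 probe sets of 16 genes (camera adjusted p = 0.26 with an estimated correlation). Many of these probe sets had wild-type intensities near or below the added constant of 16, which shrinks their log2 differences. This mean is therefore not directly comparable with the plastid ribosomal mean. The brightest in wild type, picked after values were seen, were cox1, nad4, orfX, ccb382 and ccb452. Their log2 differences were -0.05, 1.04, 0.83, 0.77 and 0.78. Late seed maturation genes had a mean of -0.32 over 22 (camera adjusted p = 0.79 with an estimated correlation), which was -0.0041 with the term for the 3 arrays.

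For the plastid ribosomal proteins, 1 of 35 splits gave a mean as far from 0, the real one, and the others ran from -0.49 to 0.40, which excludes nothing because the list was made for standing out in the real split; among the 18 splits that keep 1 of the 3 arrays in the smaller group they ran from -0.46 to 0.37, but 18 are too few for a share under 0.05. A term for the 3 arrays that stand apart moved the mean from 0.56 (SD 0.22) to 0.54 (SD 0.20), which argues against their uneven spread as the source of the mean, although with an estimated correlation the list no longer passed in that fit, whose unadjusted p was 0.015 against 0.0071 without the term, with 1 residual degree of freedom fewer. More plastid RNA of every kind may still contribute: the ribosomal mean exceeded the photosynthesis mean by 0.54, or by 0.42 with that term, 7 of 35 splits gave a difference as far from 0 as 0.54, 4 of them above 0 with the real one, and the other splits ran from -0.79 to 0.74; of the 18 splits 1 did, the real one, with 0.40 in the highest other. Organelle transcripts carried over or primed differently stay open too, since the mitochondrial mean of 0.32 was matched in distance from 0 by 6 of 35 splits, 3 of them above 0 with the real one, and by 2 of the 18; an earlier rule, a mean above 2 standard errors across probe sets (standard error 0.072), would have counted it in favour, and was replaced after its outcome was known because probe sets are not replicates. A higher level of plastid ribosomal protein transcripts in myb5 seeds is therefore only a hypothesis, and the GAPDH 5'/3' ratio that separated the genotypes leaves RNA quality open beside it.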
